A study of Mus musculus with 24 samples.

How the data were processed

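RNA of 24 B16-F10 tumours was measured on NanoString nCounter with an XT probe panel by a service company, per the labels' protocols. The panel's name, lane settings and counting software are not given in the sources used here. The deposited raw table holds a whole-number barcode count per probe and tumour, for 782 endogenous, 12 housekeeping, 8 negative-control and 6 positive-control probes, as its own probe classes state. Counts in it had been neither scaled nor background-corrected by the authors, as far as the values show, since they are whole and their totals differ between libraries. A further deposited table holds log2 values of the 782 endogenous genes. In every library the authors' log2 value equals log2 of the raw count minus 1 constant (largest spread within a library 9.95e-14, tolerance 1e-09), and that constant matched the mean log2 count of Abcf1, Polr2a, Ppia, Sdha, Tbp and Ubb up to an offset common to all libraries. This was found from the values by trying 4095 sets of housekeeping genes, the next best set having an SD of 0.0236, and no background had been subtracted. Another deposited table of log2 values was identical to it (largest difference 0).

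Tumours were grouped by the group label, and replicates were numbered in the order of their records, so numbers pair nothing. The design text speaks of 5 controls but gives n = 4, and 4 control libraries were analysed here. All 46 within-group pairs of libraries differed by more than counting noise (chi-square per degree of freedom from 3.88 to 209), so none was treated as a duplicate. Probe names came from the raw table, and 760 matched a mouse gene by accession and 27 by symbol in the GRCm38.p6 RefSeq gene table, while 7 matched none. No coordinates are given because hybridisation probes were counted, not genome positions. Summed endogenous and housekeeping counts were 694742 to 797785 in controls, 749182 to 1260750 and 707513 to 1074700 at day 2 after uniform field and microbeams, and 756140 to 898413 and 231759 to 520575 at day 7. Negative-control probes averaged 8.38 to 18.9 counts per library. A gene counted as below background in a group when no library exceeded the mean plus 2 SD of its negative controls. Its fold change is then given as at least the mean of the brighter group over the dimmer group's mean background threshold, both housekeeping-scaled.

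Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the raw counts. All 24 libraries entered 1 fit with a mean per group, so the groups shared an estimate of the spread. Library sizes were scaled to the geometric mean of the 12 housekeeping genes, each with a mean count over 50, without background subtraction. Genes with at least 20 raw counts in at least 4 libraries were kept, which left 730. P-values were adjusted by the Benjamini-Hochberg method within each of 9 comparisons at a false discovery rate (FDR) of 0.05. Of 28 gene lists for immune cells, pathways and other cell types, 24 had at least 3 tested genes and were tested with fry of limma 3.58.1 on log2 housekeeping-scaled counts (prior count 1). Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Camera with an estimated correlation, which does compare, was run beside it, and gave every adjusted p marked as with an estimated correlation. Named genes were the 8 highest and 8 lowest fold changes among called genes of each comparison, up to 3 members with the smallest adjusted p in each list discussed, and 15 immune and cell cycle genes in the first 4 comparisons, of which 5 (Cxcl10, Adgre1, Ly6g, Cdkn1a and Mki67) had no probe used here. The text gives a part of the genes so picked, and some results are not reported here. Groups, tests, lists, this rule and the first set of other settings were set before the data were examined, whereas which lists to discuss was decided after their values were seen, beside the counts over all 24 lists.

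On simulated counts for the 730 genes, with 100 genes changed at each of 2 sizes, edgeR recovered 78% at a log2 fold of 1 and 98% at 2 for microbeams against controls at day 2, with 8 false calls (4.35% of calls). For microbeams against uniform field at day 7 it recovered 74% and 99%, with 10 false calls (5.46%). These rates omit errors of scaling. Measures of single libraries were compared with exact two-sided permutation tests (R 4.3.3), adjusted over 32 tests. Other settings fixed beforehand were TMM and total-count scaling, DESeq2 1.42.0, limma on the deposited log2 values without and with a pseudocount of 10, no count filter, a filter at 50 counts or at the negative-control level, subtraction of the negative-control mean, a fit on the compared groups alone, robust dispersion, the first or last letter of the tumour titles as a covariate, and leaving out each library. Settings chosen after seeing the data were positive-control scaling, the 6 housekeeping genes of the deposited values, the inferred run as a covariate or a single inferred run, calls that held under 3 scalings, and camera on TMM-scaled values. The inferred run divides libraries at the middle of a negative-probe ratio. Microbeam tumours of day 7 had the lowest mean count, which limits the precision of their low counts. Genes under the count filter were left out, and no tumour was excluded. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.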

Results

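Expression of a mouse immune and cancer gene panel was counted in 24 melanomas on the NanoString nCounter platform, which hybridises a barcoded probe to each transcript and counts the barcodes without amplification. The tumours came from B16-F10, a pigmented melanoma line of C57BL/6 origin. In female C57BL/6 mice, 120000 cells in a thrombin and fibrinogen mixture were placed in the ear pinna and grew for 10 days before irradiation. Microbeam radiotherapy (MRT) divides a synchrotron X-ray field into parallel slices, so that tissue in the beam paths receives a peak dose and the tissue between them a much lower valley dose. Here the microbeams were 50 µm wide and 200 µm apart, with 400 Gy in the peaks and 6.2 Gy in the valleys, and a uniform field delivered 6.2 Gy throughout. Tumours were taken 2 and 7 days after microbeams (n = 5 each), 2 and 7 days after the uniform field (n = 5 each), and without irradiation 12 days after implantation (n = 4). The controls therefore match the age of the day 2 tumours, while the day 7 tumours were taken 17 days after implantation and no unirradiated tumours of that age were analysed here. The labels do not state whether each tumour came from a separate mouse, so the p-values measure the spread between these tumours.

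Endogenous totals averaged 570432 ± 37440 (SD, n = 4) in controls, 791171 ± 176323 in uniform-field tumours at day 2, 702536 ± 114481 in microbeam tumours at day 2, 702382 ± 49445 in uniform-field tumours at day 7 and 356423 ± 112125 in microbeam tumours at day 7 (SD, n = 5 each). The log2 ratio of the housekeeping to the positive-control geometric mean was 0.81 ± 0.08 in controls, 1.42 ± 0.24 and 1.0 ± 0.40 at day 2 after uniform field and microbeams, and 1.23 ± 0.23 and -0.23 ± 0.40 at day 7. At day 7 the difference between microbeams and uniform field in this ratio was -1.46, with all 12 housekeeping genes between -2.72 and -0.71. An exact permutation test on the ratio gave two-sided p = 0.00794, the smallest possible with 252 splits and 0.0317 after adjustment over 32 tests. Uniform-field tumours at day 2 had a ratio 0.61 above the controls (exact two-sided p = 0.0159, adjusted 0.0391). Counts below are scaled on the 12 housekeeping genes, fold changes are log2 values ± SE from edgeR, and a value marked relative is the same fold change minus the median over the 730 tested genes of that comparison. Calls counted under 3 scalings passed with housekeeping, TMM and total-count scaling alike.

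Libraries were also divided into 2 sets of 12 at the middle of the ratio of 3 probes without a mouse target (negative probes G and H and an LCMV probe) to the other 6 negative probes, so the equal sizes follow from the division. The ratio ran from 0.437 to 0.887 in one set and 1.0 to 2.58 in the other, with no wide gap between them. The lower set held the controls, all microbeam tumours of day 2 and uniform-field replicates 1 to 3 of day 2, and the higher set held uniform-field replicates 4 and 5 of day 2 and all day 7 tumours. The labels give no run, so this division is an uncertain inference, termed the inferred run.

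**Figure D1:**
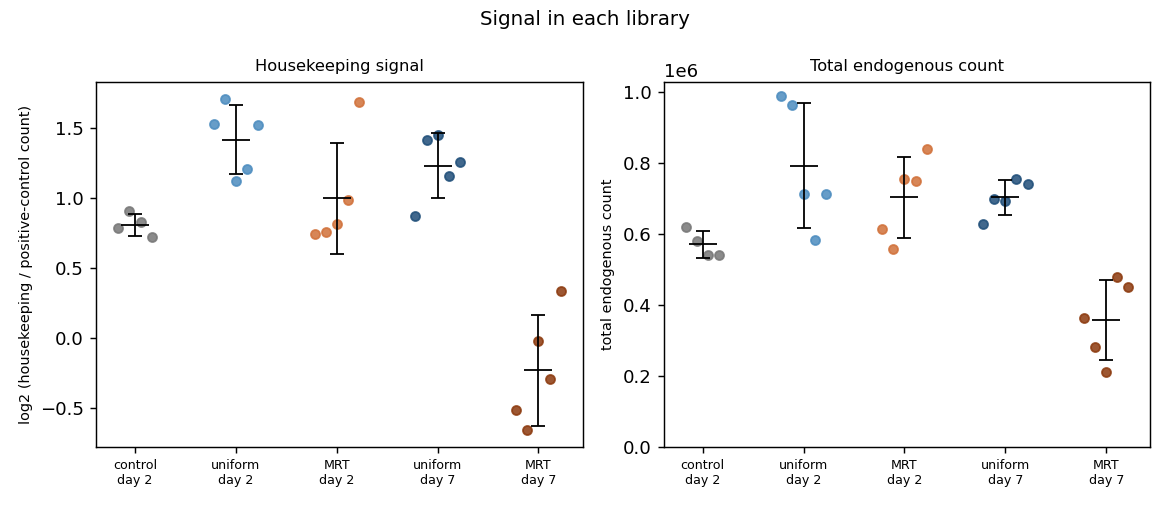
Log2 ratio of housekeeping to positive-control geometric means (left) and total endogenous count (right) of each of the 24 libraries by group, points being tumours, black marks group means and bars SD. The microbeam tumours of day 7 had the lowest group means, -0.23 for the ratio and 356423 for the total.

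The first question was what microbeams changed within 2 days, against unirradiated tumours of the same age. Many genes induced by interferons rose. Ifit3/3b, whose probe reads a pair of near-identical antiviral genes, went from 292 ± 316 scaled counts in controls (SD, n = 4) to 7054 ± 4559 after microbeams (SD, n = 5), a log2 fold change of 4.59 ± 0.86 (4.27 relative) with an adjusted p of 0.000335 (edgeR). Ifit1, which binds viral RNA, rose by 3.95 ± 0.61 (3.63 relative), the antiviral GTPase Mx1 by 3.81 ± 0.76 (3.49 relative), and the antiviral enzyme Rsad2 by 3.59 ± 0.59 (3.27 relative). The deepest falls were in Pycr1, an enzyme of proline synthesis, at -1.83 ± 0.27 (-2.15 relative), and in Uhrf1, which maintains DNA methylation through replication, at -1.42 ± 0.25 (-1.74 relative). Subunits of the replicative helicase, Mcm7 and Mcm5, fell with fold changes of -1.29 ± 0.19 (-1.62 relative) and -1.23 ± 0.20 (-1.56 relative), and the stress-response transcription factor Atf4 with -1.10 ± 0.13 (-1.43 relative).

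All 10 tested genes of the type I interferon response rose over all genes and adjusted over the list alone, with a median of 3.13 and 2.82 under TMM scaling. The list's fry adjusted p was 0.000111, and adjusted p = 0.738 in camera, which compares the list with the other genes. Of the interferon gamma response, 11 of 13 genes rose, and 11 adjusted over the list alone, with a median of 2.90. In fry the list had adjusted p = 0.00202, and adjusted p = 0.749 in camera. Its members included Cd274, the checkpoint ligand PD-L1, at 3.31 ± 0.72 (2.99 relative). All 8 MHC class I genes rose, as did 7 of 8 MHC class II genes, with 8 and 7 adjusted over the list alone and medians of 2.51 and 2.55. Their fry adjusted p was 0.000818 and 0.00313, and for both lists adjusted p = 0.749 in camera. The class I chains H2-D1 and H2-K1 rose by 2.35 ± 0.48 (2.03 relative) and 2.80 ± 0.60 (2.47 relative), and the class II chain H2-Aa by 2.65 ± 0.58 (2.33 relative).

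All 8 monocyte and macrophage genes rose, also adjusted over the list alone, with a median of 1.57. By fry, adjusted p was 4.95e-05, and adjusted p = 0.738 in camera. The lysosomal marker Cd68 rose by 1.61 ± 0.22 (1.29 relative) and the monocyte chemokine receptor Ccr2 by 2.14 ± 0.43 (1.82 relative). Acute inflammation genes rose in 10 of 16 cases, and 11 adjusted over the list alone, with a median of 0.97. By fry the list had adjusted p = 0.000218, and adjusted p = 0.749 in camera. Among them were the cytokine Lif at 1.39 ± 0.15 (1.07 relative), interleukin 18 at 2.01 ± 0.30 and the interleukin 1 receptor antagonist Il1rn at 1.47 ± 0.24. Of the p53 targets, 5 of 7 rose, 3 under 3 scalings, and 5 adjusted over the list alone, with a median of 0.72 and 0.44 under TMM scaling. Fry gave adjusted p = 3.12e-06, and adjusted p = 0.738 in camera. The death receptor Tnfrsf10b rose by 1.32 ± 0.14 (1.0 relative). All 3 tested proliferation genes, the mitotic kinase Ttk (-1.10 ± 0.18), the mitotic activator Cdc20 (-0.89 ± 0.21) and cyclin Ccnb1 (-0.84 ± 0.22, not past with positive-control scaling), fell over all genes and adjusted over the list alone, with a list median of -0.89. The list's fry adjusted p was 0.000111, and adjusted p = 0.493 in camera.

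Lymphocyte genes moved less evenly. Control means were near background, at 4.13 (T cells) and 3.84 (cytotoxic effectors) log2 scaled counts. Thresholds there were 14.8 to 20.2 raw counts, so missing calls do not exclude a rise. Cytotoxic effector genes rose in 7 of 15 cases, and 7 adjusted over the list alone, with a median of 1.59. In fry the list had adjusted p = 0.0205, and adjusted p = 0.761 in camera. Natural killer cell genes rose in 3 of 5 cases (4 adjusted over the list alone), with a median of 1.48. By fry, adjusted p was 0.013, and adjusted p = 0.749 in camera. The activating receptor Klrk1 rose by 2.78 ± 0.68 (2.46 relative), the granule protease Gzma by 2.80 ± 0.65 (2.47 relative) and the cytokine Ifng by 2.56 ± 0.68 (2.24 relative). Gzmb was below background in all 4 controls and averaged 52.6 ± 52.5 scaled counts after microbeams, at least 2.48-fold higher, with an adjusted p of 0.0211. T cell genes rose in 2 of 14 cases (1 under 3 scalings, 1 adjusted over the list alone), with a median of 0.87 and 0.58 under TMM scaling, where the list no longer passed (fry adjusted p = 0.0409 and 0.1, adjusted p = 0.794 with an estimated correlation). Cd8a (0.52 ± 0.56), Cd4 (0.95 ± 0.48), Foxp3 (0.35 ± 0.27) and Pdcd1 (0.52 ± 0.49) did not pass. Gzmb lost its call without control replicates 3 or 4 or microbeam replicate 4 (adjusted p = 0.0519, 0.0572 and 0.115). The cytotoxic list lost its call without control replicate 4 or microbeam replicates 3 or 4 (0.0539, 0.0529 and 0.0574). The T cell list lost its call without control replicates 2, 3 or 4 (0.0845, 0.0617 and 0.106) or microbeam replicates 3 or 4 (0.089 and 0.122).

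Regulatory T cell genes rose in 6 of 9 cases, and 6 adjusted over the list alone, with a median of 0.84, 0.55 with TMM. By fry the list had adjusted p = 0.00532, and adjusted p = 0.749 in camera. Those with the smallest p are shared with other cells: the ectonucleotidase Entpd1 (1.30 ± 0.30), the costimulator Icos (1.37 ± 0.37) and the cytokine Tgfb1 (0.62 ± 0.16, not past with DESeq2). Immune checkpoint genes rose in 6 of 14 cases (6 adjusted over the list alone), with a median of 0.81 that was 0.51 with TMM and 0.49 without microbeam replicate 4. Fry gave adjusted p = 0.0116, and adjusted p = 0.749 in camera. The checkpoint gene Vsir rose by 1.81 ± 0.38 (1.49 relative) and the galectin Lgals9 by 1.03 ± 0.19 (0.71 relative). The chemokines Cxcl9 and Ccl2 rose by 3.45 ± 1.04 (3.12 relative) and 1.33 ± 0.37 (1.01 relative), and the fold change of Cxcl9 was 5.74 without control replicate 1. Itgax, a dendritic cell integrin, rose by 0.58 ± 0.18 (0.26 relative), a call that ended without control replicate 3 (adjusted p = 0.0534) and under TMM scaling (adjusted p = 0.0753). Of 4 DNA repair genes 1 fell, the checkpoint kinase Chek1 (-1.03 ± 0.17, -1.35 relative), also adjusted over the list alone. The repair list had a median of -0.01, -0.27 with TMM, and a mean of -0.17 (fry adjusted p = 0.0265 for a fall, adjusted p = 0.738 with an estimated correlation), and the sign of its median turned with 6 housekeeping genes (0.02), on the deposited values (0.02), with positive-control scaling (0.23) and without control replicate 1 (0.02), control replicate 4 (0.00), microbeam replicate 1 (0.01) or microbeam replicate 4 (0.01). The first 3 of these libraries also ended the list's call when left out (0.0914, 0.0833 and 0.0747).

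In total, edgeR called 261 of 730 genes higher and 71 lower after microbeams, with a median fold change of 0.32 over all tested genes. The corresponding numbers were 200 and 151 with TMM scaling, 214 and 117 with total counts, 169 and 202 with DESeq2 and 289 and 16 with the positive controls, so the majority turned with DESeq2. Of these calls, 199 higher and 71 lower held under 3 scalings. Of 24 gene lists, 20 moved up and 2 down, and none passed in camera.

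**Figure D2:**
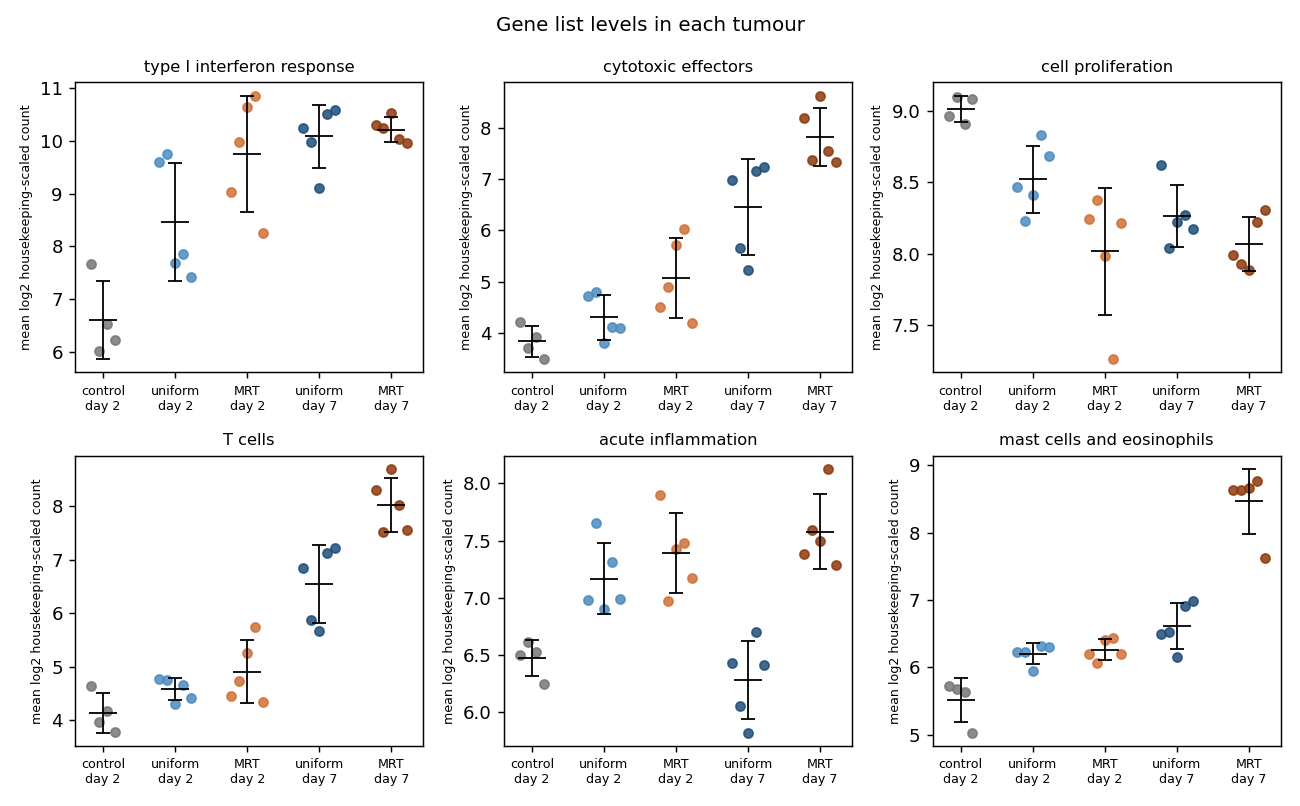
Mean log2 housekeeping-scaled count over the tested genes of 6 lists in each tumour, by group, with points for tumours, black marks for group means and bars for SD. The type I interferon response mean was 6.60 ± 0.74 in controls and 9.75 ± 1.10 in microbeam tumours at day 2, and the T cell mean was 4.58 ± 0.21 and 6.55 ± 0.73 in uniform-field tumours at day 2 and day 7.

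The uniform field of 6.2 Gy was compared with the same controls to ask what the valley dose alone changed within 2 days. Some interferon-induced genes rose too. Ifit1 went from 68 ± 50.9 scaled counts (SD, n = 4) to 596 ± 455 (SD, n = 5), a fold change of 3.13 ± 0.58 (2.92 relative) with an adjusted p of 0.00187 (edgeR). Ifit3/3b rose by 3.40 ± 0.81 (3.19 relative), Rsad2 by 2.36 ± 0.56 (2.15 relative) and the T cell attracting chemokine Ccl5 by 2.18 ± 0.50 (1.97 relative). Lower after the uniform field were Pycr1 at -1.25 ± 0.26 (-1.46 relative), the cell cycle kinase Pkmyt1 at -0.73 ± 0.17 (-0.94 relative) and the Wnt receptor Fzd7 at -0.65 ± 0.16 (-0.86 relative), and of these Pkmyt1 and Fzd7 did not pass with positive-control scaling.

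Type I interferon response genes rose in 6 of 10 cases, and 10 adjusted over the list alone, with a median of 2.01. The list's fry adjusted p was 0.0134, and adjusted p = 0.641 in camera. Monocyte and macrophage genes rose in 5 of 8 cases (8 adjusted over the list alone), with a median of 1.13, and neutrophil genes in 4 of 6 (4 adjusted over the list alone), with a median of 1.07. Acute inflammation genes rose in 5 of 16 cases (8 adjusted over the list alone), with a median of 0.76. Each of these 3 lists had a fry adjusted p of 0.00556 and adjusted p = 0.641 in camera. The signalling receptor Cd84 rose by 1.13 ± 0.25 (0.92 relative), the granulocyte growth factor receptor Csf3r by 1.37 ± 0.30 (1.16 relative), Lif by 0.89 ± 0.14 (0.68 relative) and Il18 by 1.22 ± 0.29 (1.01 relative). P53 targets rose in 3 of 7 cases (1 under 3 scalings, 4 adjusted over the list alone), with a median of 0.37, 0.20 with TMM, and Tnfrsf10b at 1.01 ± 0.14 (0.80 relative). In fry the list had adjusted p = 0.000489, and adjusted p = 0.641 in camera.

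Mast cell and eosinophil genes rose in 2 of 8 cases (4 adjusted over the list alone), with the histamine-forming enzyme Hdc at 1.10 ± 0.25 (0.89 relative) and a median of 0.75. By fry, adjusted p was 0.0134, and adjusted p = 0.745 in camera. Alternative macrophage activation genes rose in 2 of 7 cases (4 adjusted over the list alone), with a median of 0.41 that was 0.23 with TMM and 0.68 without control replicate 3. By fry the list had adjusted p = 0.02, and adjusted p = 0.77 in camera. Of 3 proliferation genes, 1 fell over all genes and 2 adjusted over the list alone, with a median of -0.55 that turned to 0.07 with positive-control scaling. Fry gave adjusted p = 0.0387 for a fall, and adjusted p = 0.641 in camera. Ifng (1.24 ± 0.67), Cxcl9 (2.00 ± 0.98), Gzmb (below background in all controls), Cd8a (-0.04 ± 0.56), Cd4 (0.45 ± 0.48), Ccl2 (0.57 ± 0.36), Foxp3 (0.32 ± 0.27), Pdcd1 (-0.03 ± 0.49) and Itgax (0.22 ± 0.18) did not pass. Cd274 rose by 2.05 ± 0.68 (1.84 relative) at an adjusted p of 0.0498, which was 0.128, 0.124 and 0.157 without control replicates 2, 3 and 4, and 0.102 and 0.166 without uniform-field replicates 1 and 2. Without control replicate 4, the lists of type I interferon (0.0547), mast cells (0.0847) and alternative macrophage activation (0.104) no longer passed. The proliferation list did not pass without control replicate 2 (0.0934), control replicate 4 (0.104) or uniform-field replicates 1, 2 and 3 (0.0704, 0.113 and 0.0591).

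In all, 80 genes were higher and 20 lower, with a median fold change of 0.21 over tested genes. These numbers became 64 and 49 with TMM scaling, 85 and 28 with total counts, 54 and 101 with DESeq2 and 546 and 1 with the positive controls, so the majority turned with DESeq2. Of 24 lists, 7 moved up and 1 down, and none passed in camera. The higher count was 122 without control replicate 1, 37, 39 and 25 without control replicates 2, 3 and 4, and 34 without uniform-field replicate 2, while the lower count was 13 and 10 without control replicates 3 and 4. Within the first inferred run, which holds 3 of the 5 uniform-field tumours, 50 genes were higher and 13 lower, with Ifit1 at 3.61 and the type I interferon list at a median of 2.49.

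Microbeams and the uniform field were then set against each other at day 2, where the valley dose of the former equals the dose of the latter. Cpt1c, a carnitine palmitoyltransferase family member, was higher after microbeams, at 618 ± 66.2 scaled counts against 356 ± 36.3 (SD, n = 5 each), a fold change of 0.80 ± 0.11 (0.68 relative) with an adjusted p of 0.000179 (edgeR). The survival gene Bcl2l1 was higher by 0.56 ± 0.08 (0.44 relative). Lower after microbeams were the chromatin protein Hmgb1 at -0.47 ± 0.08 (-0.58 relative), the cohesin subunit Smc3 at -0.46 ± 0.08 (-0.58 relative) and the acetyltransferase Naa50 at -0.46 ± 0.09 (-0.58 relative). Under TMM scaling Bcl2l1 (adjusted p = 0.0678) and Naa50 (adjusted p = 0.0914) did not pass, and with positive-control scaling neither Cpt1c nor Bcl2l1 did. Calls of these 5 genes held with any single library left out, and each of the other 11 genes picked by the naming rule lost its call without at least 1 library. Type I interferon genes had a median of 1.24, with 0 of 10 higher over all genes and 5 adjusted over the list alone, and the list did not pass (fry adjusted p = 0.148). MHC class II genes had a median of 1.31 with 0 called over all genes, and adjusted over the list alone 7 higher and 1 lower, H2-Ob at -0.54 ± 0.24 (fry adjusted p = 0.256), and cytotoxic effectors 1.15 with 0 and 0 (0.275). Monocyte and macrophage genes had a median of 0.67 with 1 higher over all genes and 3 adjusted over the list alone (0.171), and proliferation genes -0.54 with 0 and 2 lower (0.148). Cd274 (1.26 ± 0.61), Gzmb (1.62 ± 0.64), Ifng (1.32 ± 0.57), Cxcl9 (1.45 ± 0.88), Ccl2 (0.76 ± 0.34), Cd8a (0.56 ± 0.51), Cd4 (0.50 ± 0.43), Pdcd1 (0.55 ± 0.45), Foxp3 (0.02 ± 0.25) and Itgax (0.37 ± 0.17) did not pass.

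The test called 12 genes higher and 20 lower after microbeams, 209 genes had an unadjusted p under 0.05, and the median fold change was 0.11. The higher and lower counts were 9 and 5 with TMM scaling, 10 and 9 with total counts, 22 and 12 with DESeq2 and 0 and 21 with the positive controls, so that the majority turned with TMM, total counts and DESeq2, and they were 11 and 11 with 6 of the housekeeping genes. None of the 24 lists passed in fry, with TMM scaling or in camera. The higher count was 2 without uniform-field replicates 3, 4 or 5 or microbeam replicates 3 or 4, 6 without microbeam replicate 2, 23 without uniform-field replicate 1, 21 without microbeam replicate 1 and 59 without microbeam replicate 5. The lower count was 13 without uniform-field replicate 3 or microbeam replicate 2, 6 and 4 without uniform-field replicates 4 and 5, and 3 and 4 without microbeam replicates 3 and 4. With the inferred run as a covariate 2 genes were higher (Cpt1c and Bcl2l1) and 2 lower (Hmgb1 and Smc3), and within the first run 2 were higher (Cpt1c and Bcl2l1) and 0 lower.

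At day 7 the same direct comparison asked how microbeam and uniform-field tumours of equal age differed. On the housekeeping scale the median tested gene stood 0.93 higher in microbeam tumours. Relative values take it as 0 and were not tested. Above that median stood Il1rl1, the interleukin 33 receptor of mast cells and other type 2 immune cells, which went from 97.0 ± 37.9 to 759.9 ± 331 scaled counts (SD, n = 5 each), a fold change of 2.97 ± 0.37 (2.04 relative) with an adjusted p of 1.54e-06 (edgeR). The haemoglobin scavenger receptor Cd163 was at 2.55 ± 0.44 (1.62 relative), the Wnt antagonist Sfrp1 at 2.51 ± 0.35 (1.58 relative), the mesenchymal transcription factor Twist1 at 2.30 ± 0.29 (1.38 relative) and the growth factor receptor Egfr at 2.28 ± 0.29 (1.36 relative). Kcnk2, a potassium channel, and Aldh1a3, which forms retinoic acid, were below background in all 5 uniform-field tumours and at least 2.96-fold and 2.71-fold higher after microbeams. Furthest below the median were the sialyltransferase St3gal6 at -1.76 ± 0.19 (-2.69 relative), the fatty acid activating enzyme Acsl3 at -1.72 ± 0.19 (-2.64 relative), Uhrf1 at -1.16 ± 0.24 (-2.08 relative) and the mitochondrial coactivator Ppargc1a at -1.06 ± 0.30 (-1.99 relative), all also lower with TMM, total-count and positive-control scaling. With positive-control scaling Cd163 did not pass (0.94, adjusted p = 0.063), and the other genes named above did.

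The mast cell, keratinocyte and fibroblast lists were higher under housekeeping and TMM scaling. Mast cell and eosinophil genes were higher in 8 of 8 cases, 6 under 3 scalings and 8 adjusted over the list alone, with a median of 1.86, 0.91 with TMM and 0.36 with positive-control scaling. The list's fry adjusted p was 1.36e-07 and 1.43e-06 with TMM, and adjusted p = 0.987 in camera. All 3 keratinocyte and epithelial genes were higher, also under 3 scalings and adjusted over the list alone, with a median of 1.92, 0.93 and 0.38 under the same scalings. In fry the list had adjusted p = 1.41e-06 and 0.000213 with TMM, and adjusted p = 0.987 in camera. They were the epithelial adhesion molecule Cdh1 at 1.92 ± 0.28 (0.99 relative), the keratinocyte gene Sfn at 2.16 ± 0.23 (1.23 relative) and the integrin Itga6 at 1.52 ± 0.19 (0.59 relative), the last of which turned to -0.03 with positive-control scaling. All 6 fibroblast and matrix genes were higher, 4 under 3 scalings and 6 adjusted over the list alone, with a median of 1.78, 0.78 and 0.24. By fry, adjusted p was 5.14e-06 and 0.00569 with TMM, and adjusted p = 0.987 in camera. The protease inhibitor Timp1 was at 1.82 ± 0.20 (0.89 relative) and the growth factor receptors Pdgfra and Pdgfrb at 1.91 ± 0.28 (0.99 relative) and 1.74 ± 0.26 (0.81 relative). Of members named, only Sfn and Il1rl1 passed with positive-control scaling, and none of these 3 lists did.

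Lists of other immune cells were also higher on the housekeeping scale. T cell genes were higher in 13 of 14 cases (5 under 3 scalings, 13 adjusted over the list alone), with a median of 1.42 that was 0.55 with TMM and 0.05 with positive-control scaling. By fry the list had adjusted p = 0.00023 and 0.0826 with TMM, and adjusted p = 0.987 in camera. Cd4 was at 1.89 ± 0.40 (0.97 relative), the costimulator Cd28 at 1.93 ± 0.30 (1.01 relative) and Foxp3, the transcription factor of regulatory T cells, at 1.58 ± 0.24 (0.65 relative), and all 3 passed with TMM scaling too. Cytotoxic effectors were higher in 8 of 15 cases (3 under 3 scalings, 8 adjusted over the list alone), with a median of 1.30, 0.43 with TMM, -0.14 with positive-control scaling and 0.84 without microbeam replicate 3. Fry gave adjusted p = 0.000998 and 0.189 with TMM, and adjusted p = 0.993 in camera. Dendritic cell genes were higher in 9 of 10 cases (4 under 3 scalings, 9 adjusted over the list alone) and neutrophil genes in 6 of 6 (3 under 3 scalings, 6 adjusted over the list alone), with medians of 1.38 and 1.5, 0.47 and 0.57 with TMM, and -0.12 and 0.03 with positive-control scaling. Their fry adjusted p was 9.08e-06 and 9.05e-06, 0.00882 and 0.00704 with TMM, and for both adjusted p = 0.987 in camera. The chemokine Ccl22 was at 1.84 ± 0.25 (0.92 relative), the costimulator Cd80 at 1.68 ± 0.23 (0.75 relative) and Csf3r at 1.66 ± 0.27 (0.74 relative). With positive-control scaling none of Cd4, Cd28, Foxp3, Ccl22, Cd80 and Csf3r passed. Pdcd1 at 1.55 ± 0.42 (0.62 relative) and Itgax at 1.01 ± 0.17 (0.09 relative) passed on the housekeeping scale but not with TMM, and Itgax turned to -0.47 with positive-control scaling. Cd8a (0.58 ± 0.45), Gzmb (0.80 ± 0.59), Ifng (0.76 ± 0.56), Cd274 (0.68 ± 0.60), Cxcl9 (0.50 ± 0.86) and Ccl2 (0.53 ± 0.34) did not pass on the housekeeping scale and had relative values between -0.43 and -0.13.

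Interferon, damage and division lists had medians below that of all tested genes. No type I interferon gene of 10 passed, over all genes or adjusted over the list alone, and the median was 0.01, -0.86 with TMM (fry adjusted p = 0.821 and 0.175). P53 targets were higher in 4 of 7 cases (2 under 3 scalings, 4 adjusted over the list alone) with a median of 0.67 (fry adjusted p = 9.65e-05, adjusted p = 0.987 with an estimated correlation), which turned to -0.28 with TMM (fry adjusted p = 0.00449 for a fall, adjusted p = 0.684 with an estimated correlation) and -0.84 with positive-control scaling. Within this list the death receptor Fas was at 1.92 ± 0.27 (0.99 relative) and Gadd45a, a growth arrest gene, at 0.90 ± 0.18 (-0.03 relative), which was -0.06 with TMM, -0.13 with DESeq2 and -0.61 with positive-control scaling. Proliferation genes had a median of 0.19 and a mean of -0.19 with fry pointing down (adjusted p = 0.506), and a median of -0.69 with TMM (fry adjusted p = 0.00114, adjusted p = 0.668 with an estimated correlation), where 1 of 3, Ccnb1, was lower over all genes and 1 adjusted over the list alone. DNA repair genes fell as a list, with a median of -0.19 and -1.08 with TMM (fry adjusted p = 0.00936 and 2.32e-07, adjusted p = 0.118 with an estimated correlation), and the median turned to 0.07 with 6 housekeeping genes and 0.08 on the deposited values. Of its 4 genes 1 fell, Chek1 (-0.75 ± 0.17, -1.68 relative), and 1 was higher, against 1 lower and 0 higher adjusted over the list alone. The gene that was higher, the damage-sensing kinase Atr (0.19 ± 0.09, -0.73 relative), was lower with TMM (-0.71), total-count (-0.35), DESeq2 (-0.76) and positive-control scaling (-1.25). Atr also lost its call without uniform-field replicates 2, 3 or 4 or microbeam replicates 1, 2 or 4 (adjusted p = 0.0937, 0.111, 0.0672, 0.0664, 0.101 and 0.118).

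Over the panel 532 genes were called higher and 55 lower, against 176 and 226 with TMM scaling, 297 and 145 with total counts, 164 and 242 with DESeq2 and 11 and 304 with the positive controls, so the majority direction turned with TMM, DESeq2 and positive-control scaling. Calls under 3 scalings numbered 176 higher and 55 lower. Of 24 lists 21 moved up and 1 down with housekeeping scaling, 7 up and 3 down with TMM, and none in camera. All 10 tumours lay in the same inferred run.

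**Figure D3:**
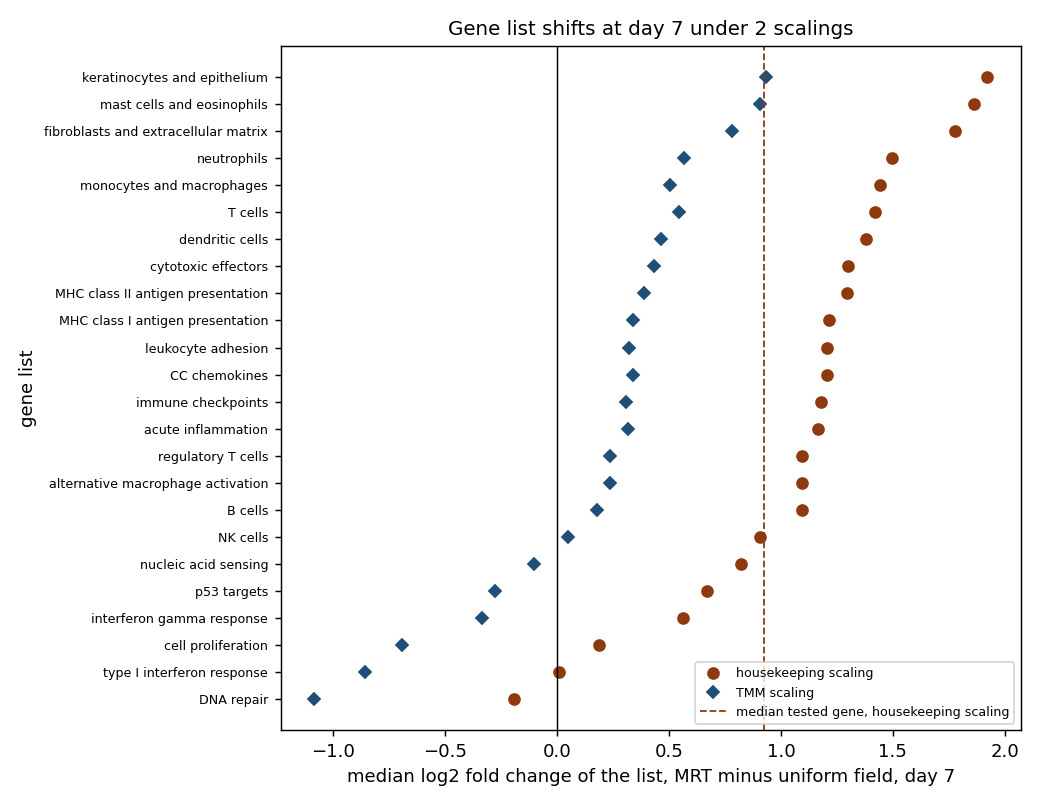
Median log2 fold change of each tested gene list in microbeam minus uniform-field tumours at day 7 (n = 5 each), with housekeeping and with TMM scaling as separate points, and the median of all tested genes as a dashed line. The mast cell and eosinophil list lay at 1.86 and 0.91, and the p53 target list at 0.67 and -0.28, a change of sign.

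Change with time was examined within each irradiation, where tumour age differs along with days since exposure. From day 2 to day 7 after the uniform field, lymphocyte genes rose and Cxcl1, Cxcl2 and Cxcl3 fell. Nkg7, a granule protein of cytotoxic cells, went from 44.5 ± 15.7 to 512 ± 333 scaled counts (SD, n = 5 each), a fold change of 3.51 ± 0.59 (3.01 relative) with an adjusted p of 5.47e-05 (edgeR). The CD8 chain Cd8b1 rose by 3.70 ± 0.71 (3.20 relative), the T cell receptor component Cd3d by 3.31 ± 0.58 (2.81 relative), perforin (Prf1) by 3.26 ± 0.60 (2.76 relative) and Gzmb by 3.09 ± 0.65 (2.59 relative). Interleukin 1 beta (Il1b) fell with -3.72 ± 0.45 (-4.22 relative), the neutrophil chemokines Cxcl2 and Cxcl1 with -3.39 ± 0.36 (-3.89 relative) and -2.65 ± 0.53 (-3.15 relative), the prostaglandin-forming enzyme Ptgs2 with -3.28 ± 0.32 (-3.78 relative) and Hdc with -2.18 ± 0.24 (-2.68 relative). Cxcl3 and Il24 dropped below background in all 5 tumours of day 7, at least 3.22-fold and 2.54-fold lower.

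T cell genes rose in 13 of 14 cases (13 adjusted over the list alone), with a median of 2.05. The list's fry adjusted p was 5.9e-05, and adjusted p = 0.777 in camera. Cytotoxic effectors rose in 14 of 15 cases (14 adjusted over the list alone), with a median of 2.53. In fry the list had adjusted p = 0.000151, and adjusted p = 0.786 in camera. All 5 natural killer cell genes and all 9 regulatory T cell genes rose, also adjusted over the list alone, with medians of 2.89 and 1.79 (fry adjusted p = 5.63e-05 and 6.08e-05, adjusted p = 0.777 for both with an estimated correlation). The natural killer receptor Ncr1 rose by 2.90 ± 0.44 and Foxp3 by 1.79 ± 0.24. B cell genes rose in 9 of 10 cases (9 adjusted over the list alone), with Cd22 at 1.82 ± 0.21, immunoglobulin Ighm at 2.66 ± 0.41 and a median of 1.32. By fry, adjusted p was 6.55e-06, and adjusted p = 0.777 in camera. Checkpoint genes rose in 13 of 14 cases (13 adjusted over the list alone), with the inhibitory receptor Tigit at 2.65 ± 0.43 and a median of 1.64. By fry the list had adjusted p = 7.18e-05, and adjusted p = 0.777 in camera. All 8 MHC class II genes rose, also adjusted over the list alone, with a median of 2.30. Fry gave adjusted p = 0.000151, and adjusted p = 0.777 in camera. Type I interferon genes rose in 6 of 10 cases (3 under 3 scalings, 7 adjusted over the list alone), with a median of 1.40 and Oas2, an RNA-sensing enzyme, at 1.88 ± 0.52. The list's fry adjusted p was 0.00853, and adjusted p = 0.827 in camera.

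Acute inflammation genes moved both ways, 7 of 16 lower and 5 higher, against 7 and 6 adjusted over the list alone, and 7 and 3 under 3 scalings, with a median of -0.61, -0.98 with TMM. In fry the list had adjusted p = 0.00143 for a fall, and adjusted p = 0.777 with an estimated correlation. Neutrophil genes fell in 4 of 6 cases and rose in 1, with 4 and 1 adjusted over the list alone and a median of -0.84. By fry, adjusted p was 0.00741 for a fall, and adjusted p = 0.777 with an estimated correlation. The member that rose, Ncf4 (1.63 ± 0.32), codes for an oxidase subunit that other phagocytes carry as well. Gene counts were 379 higher and 63 lower with a median fold change of 0.50, and 271 and 196 with TMM scaling, 292 and 126 with total counts, 255 and 234 with DESeq2 and 271 and 35 with the positive controls. Lists called by fry numbered 17 up and 2 down, none in camera. Within the inferred run that holds uniform-field replicates 4 and 5 of day 2 with all day 7 tumours, the T cell median was 2.08 (fry adjusted p = 0.00253), the type I interferon median 2.60 (0.00253) and the acute inflammation median -0.65 (0.0152).

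After microbeams, lymphocyte genes also rose from day 2 to day 7. The T cell receptor gene Trac went from 42.2 ± 20.8 to 997 ± 650.1 scaled counts (SD, n = 5 each), a fold change of 4.56 ± 0.50 (3.25 relative) with an adjusted p of 3.54e-08 (edgeR). The chemokine receptor Cxcr6 rose by 4.64 ± 0.47 (3.33 relative) and Cd4 by 4.35 ± 0.45 (3.04 relative). Apart from Cxcl3, below background in all 5 tumours of day 7, the largest falls were in St3gal6 at -2.28 ± 0.19 (-3.59 relative) and Acsl3 at -2.11 ± 0.19 (-3.42 relative), followed by Cxcl2 at -2.04 ± 0.35 (-3.35 relative) and Ptgs2 at -1.86 ± 0.31 (-3.17 relative). T cell genes rose in 13 of 14 cases (13 adjusted over the list alone), with a median of 3.31 and 2.12 with TMM. Cytotoxic effectors rose in 14 of 15 (14 adjusted over the list alone), with medians of 2.73 and 1.54, and checkpoint genes in 13 of 14 (13 adjusted over the list alone), with 2.65 and 1.41. Fry adjusted p of these 3 lists was 2.7e-08, 6.39e-07 and 5.43e-08, and adjusted p = 0.878 for each in camera. All 10 B cell genes rose, also adjusted over the list alone, with Cd22 at 2.87 ± 0.22 and a median of 2.57, 1.37 with TMM. By fry the list had adjusted p = 3.13e-10, and adjusted p = 0.878 in camera. MHC class II genes rose in 7 of 8 cases (4 under 3 scalings, 8 adjusted over the list alone), with H2-Eb1 at 3.25 ± 0.48 and a median of 2.22, 1.06 with TMM. Fry gave adjusted p = 2.56e-06, and adjusted p = 0.879 in camera.

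Inflammation and interferon lists depended on the scaling after microbeams. Acute inflammation genes were higher in 8 and lower in 4 of 16 cases, against 3 and 4 under 3 scalings and 8 and 4 adjusted over the list alone, and their median of 0.37 (fry adjusted p = 0.102) turned to -0.88 with TMM (fry adjusted p = 4.33e-05 for a fall, adjusted p = 0.664 with an estimated correlation) and -0.85 with positive-control scaling. Members that rose included Nfkbia (1.80 ± 0.21, 0.49 relative) and Tnfaip3 (1.83 ± 0.25, 0.52 relative), which restrain NF-kB signalling. Neutrophil genes were higher in 3 of 6 cases (1 under 3 scalings, 3 adjusted over the list alone), with a median of 0.60 (fry adjusted p = 0.0076, adjusted p = 0.878 with an estimated correlation) that was 0.28 without day 7 replicate 4 and turned to -0.69 with TMM (fry adjusted p = 0.0218 for a fall, adjusted p = 0.76 with an estimated correlation), -0.14 with total counts and -0.72 with positive-control scaling. Type I interferon genes had a median of 0.08 and -1.03 with TMM (fry adjusted p = 0.434 and 0.164), with 2 genes higher and 1 lower over all genes, 0 and 1 under 3 scalings and 0 and 0 adjusted over the list alone. The edgeR test called 557 genes higher and 68 lower with a median fold change of 1.31, and 296 and 277 with TMM scaling, 394 and 171 with total counts, 277 and 295 with DESeq2 and 268 and 248 with the positive controls, so the majority turned with DESeq2. Fry called 20 lists up and 0 down, 15 and 5 with TMM, and none passed in camera. The 2 time points lay in different inferred runs, so time, tumour age and run cannot be told apart here.

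Whether the contrast between irradiations changed from day 2 to day 7 was tested as an interaction, the day 7 difference between microbeams and uniform field minus the day 2 difference. That difference increased in Il1rl1 by 3.06 ± 0.50 (2.35 relative) with an adjusted p of 0.000161 (edgeR, n = 5 per group). Kcnk2 and Aldh1a3 passed too but were below background in all uniform-field tumours of day 7, and Kcnk2 also in all microbeam tumours of day 2, so their size is not measured. Cd163 was at 2.61 ± 0.59 (1.90 relative), which did not pass with positive-control scaling. The strongest decreases that held with any library left out were in Gzmc, a granule protease, at -1.85 ± 0.52 (-2.56 relative), St3gal6 at -1.71 ± 0.26 (-2.42 relative) and Acsl3 at -1.18 ± 0.26 (-1.89 relative). Mast cell and eosinophil genes increased in 7 of 8 cases (5 under 3 scalings, 7 adjusted over the list alone), with Hdc at 1.90 ± 0.33 (1.19 relative), not past with positive-control scaling, and a median of 1.81, 0.95 with TMM (fry adjusted p = 3.51e-05 and 0.000156, adjusted p = 0.982 with an estimated correlation). All 3 keratinocyte and all 6 fibroblast genes increased, also adjusted over the list alone and 2 and 3 under 3 scalings, with medians of 1.69 and 1.55 and, with TMM, 0.80 and 0.63. Their fry adjusted p was 0.000624 and 0.00105, 0.0174 and 0.0995 with TMM, and adjusted p = 0.982 for both in camera. T cell genes increased in 6 of 14 cases (1 under 3 scalings, 5 adjusted over the list alone), with a median of 1.18 (fry adjusted p = 0.0318, adjusted p = 0.982 with an estimated correlation) that was 0.40 with TMM (0.558). Type I interferon genes had a median of -1.18 (fry adjusted p = 0.19) and -1.92 with TMM, where the list passed in fry (0.0414, adjusted p = 0.906 with an estimated correlation). Of its 10 genes, 2 were lower over all genes, against 0 adjusted over the list alone, and the former, Bst2 and Ifit1, lost their calls without 11 and 13 of the 20 libraries.

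This test called 383 genes up and 38 down, with a median of 0.71, and 73 and 176 with TMM scaling, 192 and 89 with total counts, 66 and 193 with DESeq2 and 5 and 135 with the positive controls, so most calls pointed down with TMM, DESeq2 and positive-control scaling. Lists numbered 14 up and 0 down, 2 and 3 with TMM, and none in camera. The T cell list lost its call without uniform-field day 2 replicate 1 (0.0543), uniform-field day 2 replicate 2 (0.0519), microbeam day 2 replicate 1 (0.063), microbeam day 2 replicate 5 (0.0733), uniform-field day 7 replicate 2 (0.0707), uniform-field day 7 replicate 3 (0.081), microbeam day 7 replicate 1 (0.0584) or microbeam day 7 replicate 3 (0.068). With any of the first 7 of these left out, 8 lists instead of 14 passed.

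Both day 7 groups were also set against the younger controls, which leaves irradiation, tumour age and inferred run inseparable. In microbeam tumours Nkg7 was at 6.37 ± 0.75 (4.47 relative) against controls (adjusted p = 7.56e-08, edgeR, n = 5 and 4), Cxcr6 at 5.63 ± 0.55 (3.73 relative) and Trac at 5.61 ± 0.58 (3.71 relative), while Acsl3 was at -2.69 ± 0.20 (-4.59 relative) and St3gal6 at -2.31 ± 0.20 (-4.21 relative). In uniform-field tumours Ifit3/3b was at 4.67 ± 0.87 (3.92 relative) with an adjusted p of 7.54e-05 and Nkg7 at 4.34 ± 0.69 (3.60 relative), while Ptgs2 was at -3.10 ± 0.33 (-3.85 relative) and Il1b at -2.92 ± 0.45 (-3.67 relative). Microbeam tumours differed in 577 genes higher and 70 lower, with a median of 1.90, and 348 and 271 with TMM scaling, 432 and 188 with total counts, 309 and 305 with DESeq2 and 395 and 178 with the positive controls. For uniform-field tumours the counts were 438 and 70 with a median of 0.74, and 317 and 245 with TMM scaling, 362 and 155 with total counts, 274 and 281 with DESeq2 and 517 and 9 with the positive controls, so the majority turned with DESeq2. Fry called 22 lists up and 2 down after microbeams and 19 up and 1 down after the uniform field, and none passed in camera.

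**Figure D4:**
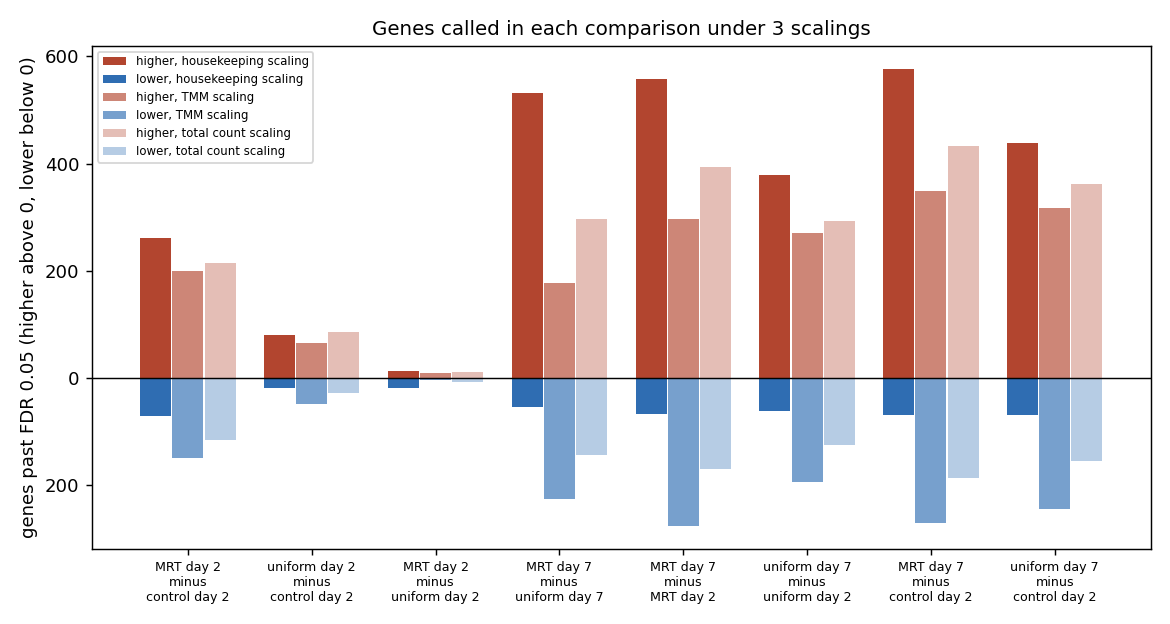
Number of genes past FDR 0.05 in 8 comparisons, higher above 0 and lower below it, under housekeeping, TMM and total-count scaling, as bars. In microbeam minus uniform-field tumours at day 7 the counts were 532 higher and 55 lower with housekeeping genes and 176 and 226 with TMM, a change of the majority direction.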

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

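Chosen only after the result was seen were the tests on the third quartile of genes by count, on the single housekeeping genes, on the tumour-cell share, on background at day 7, on single libraries, and on scaling for the mast cell, keratinocyte and fibroblast lists, along with the inferred run and positive-control scaling.

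The first pattern is the upward shift of the panel in microbeam against uniform-field tumours at day 7, a median of 0.93 that was 1.11, 1.32, 0.75 and 0.16 from the lowest to the top quartile of genes by mean count. The top quartile's median (0.15 to 0.21 with a library left out, 183 genes) met the value set beforehand for counts near background as the cause, below 0.3. Against background as the whole cause stands the third quartile, at 228 to 769 counts, whose median stayed at 0.77 (0.71 to 0.88) after the negative-control mean was subtracted. Whether a few housekeeping genes caused the shift stays open. On the positive-control scale 12 of 12 fell by more than the median endogenous gene (mean -1.46 against -0.50). That gap largely restates the shift, and the falls ran from -2.72 (Pgk1) to -0.71 (Stk11ip). A smaller share of tumour cells stays open as a hypothesis, because the gap of 0.66 between the highest and lowest of 9 cell type lists was reached in other splits of the 10 tumours too (exact permutation p = 0.27, 252 splits), which does not show that they rose alike, and no melanocyte marker of the lists had a probe used here.

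The second pattern is the rise of T cell genes (median 2.05) and fall of acute inflammation genes (median -0.61) from day 2 to day 7 after the uniform field, where neither list passed with an estimated correlation (adjusted p = 0.777 for both). A difference between the runs as inferred is argued against as the whole cause, while a run divided otherwise stays open: within the run that holds day 2 replicates 4 and 5 (2 tumours against 5), the T cell median was 2.08 (fry adjusted p = 0.00253) and the acute inflammation median -0.65 (0.0152), both past values set beforehand. These day 2 replicates had negative-probe ratios of 1.54 and 1.3, below the 1.73 to 2.58 of the uniform-field tumours of day 7. Higher mean background at day 7 is argued against for T cells, whose median was 2.78 (0.000127) with the negative-control mean subtracted. Probe-specific background stays open, since the LCMV probe rose by 1.79. Tumour age stays open and untested without unirradiated tumours of day 7. For microbeams, run, age and time cannot be told apart.

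The third pattern is the higher level of mast cell, keratinocyte and fibroblast lists in microbeam than in uniform-field tumours at day 7, with medians of 1.86, 1.92 and 1.78. Dependence on a single library is argued against, since all 3 lists kept their fry calls with each of the 10 left out, though none passed with an estimated correlation (adjusted p = 0.987 for each, and 0.457, 0.668 and 0.668 with TMM). Scaling stays open, because TMM kept the calls (largest fry adjusted p = 0.00569) while positive-control scaling ended them by shrinking the medians to 0.36, 0.38 and 0.24 (adjusted p = 0.398, 0.615 and 0.924). Ear skin taken with the tumour, hypothetically a source of Cdh1 (439.6 ± 142 and 1665 ± 789 scaled counts in uniform-field and microbeam tumours, SD, n = 5 each), Sfn (2120.1 ± 437 and 9481 ± 3842) and Itga6 (929 ± 170.5 and 2657 ± 1075), cannot be told apart from a change within the tumour. Group-centred keratinocyte and mast cell means correlated with r = -0.14 and rho = -0.38 over the 10 tumours (permutation p = 0.71 and 0.302, 0.71 and 0.302 adjusted over 5 relations), below the 0.2 set beforehand against skin but not by more than its spread, and r = -0.01 without the 2 farthest tumours.

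Each count of genes called on the housekeeping scale was set against 100 splits of the same tumours, the real one included. Chance was excluded for microbeams at day 2 against controls (332 genes, 1 split as large, highest other 288), uniform field at day 2 against controls (100, 1, 33), microbeams against uniform field at day 7 (587, 1, 547), day 7 against day 2 after microbeams (625, 1, 584) and after the uniform field (442, 1, 320), and for day 7 against controls after microbeams (647, 1, 644) and the uniform field (508, 1, 348). For the interaction (421, 2, 474) the splits cannot decide, since the one with 474 kept the day 7 groups whole and regrouped the day 2 tumours. For microbeams against uniform field at day 2 chance could not be excluded (32 genes, 5 splits as large), and the split with 120, which set microbeam replicate 5 with uniform-field replicates 2 to 5, points to a structure of the samples. Counts of lists called by fry in the same order were 22 (1 split as large, highest other 21), 8 (1, 7), 22 (1, 21), 20 (3, 23), 19 (1, 16) and, for the interaction, 14 (3, 17). Apart from the interaction, where the split with 17 also kept day 7 whole, chance was thus unlikely for each count taken singly. No list passed in camera in any comparison. Day 7 against day 2 after the uniform field called 307 genes higher and 48 lower within 1 inferred run.

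In 6 of 190 groups of values, about 1 in 20 being what chance gives, 1 tumour stood apart from the others of its group. Microbeam replicate 5 of day 2 had a log2 ratio of housekeeping to positive-control signal of 1.68 against 0.74 to 0.99 in the others. Microbeam replicate 5 of day 7 had lower mean log2 levels of the lists for MHC class I (10.64 against 11.08 to 11.19), B cells (6.40 against 6.98 to 7.06) and mast cells and eosinophils (7.62 against 8.62 to 8.77). The last list was also low in control replicate 4 (5.04 against 5.64 to 5.72) and in uniform-field replicate 3 of day 2 (5.94 against 6.23 to 6.32).

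The difference between irradiations itself differed between day 7 and day 2 in 383 genes upward, 38 downward and 14 lists upward by the interaction test on the housekeeping scale. With TMM the counts were 73 genes up and 176 down and 2 lists up and 3 down, and with positive controls 5 genes up and 135 down, so the majority turned, and no list passed with an estimated correlation. Upward genes were Il1rl1 (3.06), Kcnk2 (2.86), Aldh1a3 (2.70), Cd163 (2.61), Ifna1 (2.58), Lefty1 (2.52), Sfrp1 (2.48) and Ccl20 (2.33), and downward ones Gzmc (-1.85), Bst2 (-1.82), Ifit1 (-1.72), St3gal6 (-1.71), Gzmd (-1.49), Mlkl (-1.22), Acsl3 (-1.18) and Ppargc1a (-1.13). Kcnk2 and Aldh1a3 were below background in all uniform-field tumours of day 7, and Kcnk2 in all microbeam tumours of day 2, so these 2 values are not measured on both sides. Medians of the lists described were 1.81 for mast cells, 1.69 for keratinocytes, 1.55 for fibroblasts and 1.18 for T cells. Calls ended for Lefty1 with TMM, total counts, DESeq2 and positive controls, for Bst2, Ifit1, Gzmd, Mlkl and Ppargc1a with 6 housekeeping genes, and for Ccl20, Ifna1 and Cd163 with positive controls. With 1 of 20 tumours left out, calls ended in 11 fits for Bst2, 13 for Ifit1 and 13 for Gzmd (adjusted p up to 0.0903, 0.0763 and 0.132). They also ended without microbeam day 2 replicates 3 or 4, uniform-field day 7 replicate 1 or microbeam day 7 replicate 4 for Mlkl (adjusted p = 0.0504, 0.0547, 0.0502 and 0.0517), without uniform-field day 2 replicates 2 or 3 or microbeam day 7 replicate 4 for Lefty1 (0.0967, 0.0568 and 0.0531) and without microbeam day 2 replicate 5 for Ppargc1a (0.0549), while those of the other 10 genes held.

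Probes without a mouse target gave more counts than in any control in several groups. The LCMV probe averaged 14.6 and 39.2 counts at day 2 and day 7 after the uniform field and 26 at day 7 after microbeams, against at most 14 in a control. Negative probes G and H summed to 43.4 and 75.4 after the uniform field and 27.8 and 48 after microbeams, against at most 26.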

How the results depend on the processing

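Positive-control scaling, the set of 6 housekeeping genes, the inferred run as a covariate or as a limit, calls required under 3 scalings, and camera on TMM-scaled values were chosen after the data were seen, and the other settings before. In what follows M and U stand for microbeam and uniform field, 2 and 7 for the day and C for control, and each count is to be read against the one in the report, with the cause of a difference not tested unless the setting itself removes libraries or genes. Leaving out the count filter, a filter on the negative controls, and robust fitting moved no count of calls by more than 1.5 times, nor did the first title letter as covariate in the 12 of 18 gene counts and 8 of 14 list counts on which it was run. With TMM scaling, genes numbered 151 down in M2 minus C, 49 down in U2 minus C, 5 down in M2 minus U2, 176 up and 226 down in M7 minus U7, 296 up and 277 down in M7 minus M2, 196 down in U7 minus U2, 348 up and 271 down in M7 minus C, 245 down in U7 minus C, 73 up and 176 down in the interaction. Lists with this setting numbered 7 up and 3 down in M7 minus U7, 5 down in M7 minus M2, 4 down in U7 minus U2, 2 up and 3 down in the interaction. With total-count scaling, genes numbered 117 down in M2 minus C, 9 down in M2 minus U2, 297 up and 145 down in M7 minus U7, 171 down in M7 minus M2, 126 down in U7 minus U2, 188 down in M7 minus C, 155 down in U7 minus C, 192 up and 89 down in the interaction. Lists then numbered 14 up in U2 minus C, 2 down in M7 minus U7, 1 down in M7 minus M2, 7 up and 1 down in the interaction. With DESeq2, genes numbered 169 up and 202 down in M2 minus C, 101 down in U2 minus C, 22 up and 12 down in M2 minus U2, 164 up and 242 down in M7 minus U7, 277 up and 295 down in M7 minus M2, 234 down in U7 minus U2, 309 up and 305 down in M7 minus C, 274 up and 281 down in U7 minus C, 66 up and 193 down in the interaction. With positive-control scaling, genes numbered 16 down in M2 minus C, 546 up and 1 down in U2 minus C, 0 up in M2 minus U2, 11 up and 304 down in M7 minus U7, 268 up and 248 down in M7 minus M2, 35 down in U7 minus U2, 178 down in M7 minus C, 9 down in U7 minus C, 5 up and 135 down in the interaction. Its lists numbered 1 down in M2 minus C, 23 up and 0 down in U2 minus C, 1 down in M2 minus U2, 0 up and 4 down in M7 minus U7, 11 up and 4 down in M7 minus M2, 0 up and 1 down in the interaction. With the 6 housekeeping genes, genes numbered 11 down in M2 minus U2, 27 down in M7 minus U7, 28 down in M7 minus M2, 38 down in U7 minus U2, 32 down in M7 minus C, 12 down in the interaction. Lists with this setting numbered 0 down in M7 minus U7. With limma on the deposited values, genes numbered 11 down in M2 minus U2, 28 down in M7 minus U7, 31 down in M7 minus M2, 39 down in U7 minus U2, 33 down in M7 minus C, 13 down in the interaction. Lists then numbered 0 down in M7 minus U7. With limma and pseudocount 10, genes numbered 43 up in U2 minus C, 7 up and 11 down in M2 minus U2, 28 down in M7 minus U7, 31 down in M7 minus M2, 38 down in U7 minus U2, 32 down in M7 minus C, 14 down in the interaction. Its lists numbered 0 down in M7 minus U7. With only the compared groups fitted, genes numbered 146 up and 42 down in U2 minus C, 5 up and 13 down in M2 minus U2. Lists with this setting numbered 1 down in M2 minus C, 13 up in U2 minus C. With background subtracted, lists numbered 0 down in U2 minus C, 1 down in M7 minus M2, 7 up in the interaction. With the filter at 50 counts, lists numbered 9 up in the interaction. With the last title letter as covariate, genes numbered 2 up and 11 down in M2 minus U2. Lists then numbered 1 down in M2 minus C. With the inferred run as covariate, genes numbered 2 up and 2 down in M2 minus U2, 22 down in the interaction. Within an inferred run, genes numbered 50 up and 13 down in U2 minus C, 2 up and 0 down in M2 minus U2, 19 down in the interaction. With camera and an estimated correlation, on housekeeping-scaled or TMM-scaled values, 0 lists passed in any comparison.

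Leaving out each library in turn gave 1 to 2 lists down in M2 minus C, 25 to 122 genes up in U2 minus C, 10 to 19 genes down in U2 minus C, 4 to 14 lists up in U2 minus C, 0 to 1 lists down in U2 minus C, 2 to 59 genes up in M2 minus U2, 3 to 29 genes down in M2 minus U2, 0 to 1 lists down in M7 minus M2, 8 to 16 lists up in the interaction, where a fit with fewer libraries has fewer residual degrees of freedom. Across these fits 3124 values of named genes stayed on their side of the threshold in the same direction, 210 no longer passed, 2 newly passed and 10 changed sign without a call in either fit. Of list values 639 stayed, 24 no longer passed, 2 newly passed, 7 changed sign without a call in either fit and 4 turned with a call, all 4 in the DNA repair list of M2 minus C, whose median ranged from -0.053 to 0.015. Robust fitting left 320 named-gene values on their side and ended 1 call.

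Among named genes, the numbers that stayed on their side of the threshold in the same direction, that no longer passed, that newly passed and that changed sign without a call in either fit were 286, 24, 0 and 7 with TMM, 305, 13, 0 and 2 with total counts, 286, 21, 0 and 9 with DESeq2, 240, 54, 7 and 9 with positive-control scaling and 308, 12, 1 and 0 with 6 housekeeping genes. Fold changes or list medians with a call in either fit changed sign in the following, and the cause was not tested. Fry still pointed down for proliferation in M7 minus U7 with TMM and total counts. With TMM the sign turned in M7 minus U7 for Atr (-0.71), Gadd45a (-0.063), cell proliferation (-0.69) and p53 targets (-0.28), and in M7 minus M2 for Il1r2 (-0.54), Oas3 (-0.14), acute inflammation (-0.88) and neutrophils (-0.69). With total counts the sign turned in M7 minus U7 for Atr (-0.35) and cell proliferation (-0.34), and in M7 minus M2 for neutrophils (-0.14). With DESeq2 the sign turned in M7 minus U7 for Atr (-0.76) and Gadd45a (-0.13), and in M7 minus M2 for Il1r2 (-0.67), Oas2 (-0.079) and Oas3 (-0.24). With positive controls the sign turned in M2 minus C for DNA repair (0.23), and in U2 minus C for Mcm7 (0.028), Ttk (0.069) and cell proliferation (0.069), and in M7 minus U7 for Atr (-1.25), Ccl2 (-0.94), Gadd45a (-0.61), Itga6 (-0.029), Itgax (-0.47), Sesn1 (-0.15), Trat1 (-0.25), cell proliferation (-1.22), cytotoxic effectors (-0.14), dendritic cells (-0.12) and p53 targets (-0.84), and in M7 minus M2 for Il1r2 (-0.59), Oas3 (-0.15), acute inflammation (-0.85) and neutrophils (-0.72). With 6 housekeeping genes the sign turned in M2 minus C for DNA repair (0.017), and in M7 minus U7 for DNA repair (0.073). With limma the sign turned in M2 minus C for DNA repair (0.018), and in M7 minus U7 for DNA repair (0.078). With pseudocount 10 in limma the sign turned in M2 minus C for DNA repair (0.018), and in M7 minus U7 for DNA repair (0.076). With the run covariate the sign turned in M7 minus M2 for Ifit1 (0.70). Camera on TMM-scaled values has the medians given for TMM.

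No paired analysis was possible, as replicate numbers pair no tumours. Probes with counts near the negative-control mean limit what can be read from low genes. No fold is given where both groups lay below background.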

Other observations

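The lists and genes described first were chosen after their values were seen, and the tests on the interferon list over 10 tumours were set beforehand, while those within an inferred run were not. CC chemokines, which draw monocytes and lymphocytes, rose at day 2 after microbeams against controls in 4 of 8 genes over all genes and 4 adjusted over the list alone, where 1 was lower, with a median of 0.96. Ccl5 went from 70.0 ± 31.8 scaled counts (SD, n = 4) to 601 ± 311 (SD, n = 5), a fold change of 3.10 ± 0.52 (2.78 relative), and the monocyte attractant Ccl12 rose by 1.70 ± 0.39 (1.37 relative). Ccl3 (1.13 ± 0.41) passed, though not with TMM scaling (adjusted p = 0.0665, edgeR), and the gene lower over the list alone was Ccl20 (-0.94 ± 0.40). For the CC chemokine list the fry adjusted p was 0.00348, and adjusted p = 0.749 with an estimated correlation. Leukocyte adhesion genes rose in 4 of 7 cases (4 adjusted over the list alone), with a median of 1.49 (fry adjusted p = 0.00484, adjusted p = 0.749 with an estimated correlation). They included the endothelial ligands Icam1 (1.49 ± 0.32, 1.17 relative) and Vcam1 (1.53 ± 0.35, 1.21 relative) and the integrin chain Itgal (1.75 ± 0.51, 1.43 relative), while the endothelial selectin Sele stood at -0.07 ± 0.20 and did not pass.

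From day 2 to day 7 after the uniform field, adhesion genes rose in 5 of 7 cases (5 adjusted over the list alone), among them Icam1 by 1.75 ± 0.29 (1.25 relative), Itgal by 2.03 ± 0.44 (1.53 relative) and Vcam1 by 1.28 ± 0.31 (0.78 relative), with a list median of 1.28 and 0.88 with TMM (fry adjusted p = 0.00102, adjusted p = 0.827 with an estimated correlation).

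Type I interferon genes varied widely among the 10 irradiated tumours of day 2, and a hypothesis was that they vary together with cytotoxic effector genes. With each group centred on its mean, the 2 list means correlated with r = 0.92 and rho = 0.85 (permutation p = 0.00050 and 0.00030, 0.0025 and 0.0015 adjusted over 5 relations), and r = 0.93 without the 2 farthest tumours. Over the 8 tumours of the first inferred run r was 0.96 and rho 1 (exact permutation p = 0.00139 for both, the smallest that 720 permutations can give, adjusted 0.00347), r was 0.95 without its 2 farthest, and the other run holds 2 such tumours, too few for a value. Both lists could follow a common source of variation, such as the share of leukocytes in the sample, which was not tested. A relation with the proliferation list stayed open, at r = -0.62 and rho = -0.47 (permutation p = 0.0663 and 0.187, adjusted 0.111 and 0.233), r = -0.59 without the 2 farthest, and r = -0.54 and rho = -0.69 in the first run (exact permutation p = 0.201 and 0.11, adjusted 0.252 and 0.183), with r = -0.68 without its 2 farthest.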
